A study of Mus musculus with 2 samples.

How the data were processed

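Small RNA libraries from heart mitochondria of mice were compared, 1 control and 1 STZ library, grouped by the treatment given in the labels. Per the labels' protocols, total RNA was extracted with a phenol-based reagent, adapters were ligated to both ends, and cDNA was amplified by PCR and purified on a gel. No molecular identifiers are mentioned there. The genome build was GRCm39, per the submitters' processing notes. The aligner, the miRNA reference, the adapter trimming and the number of mismatches allowed are not given in the sources used here.

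The deposited files hold, for each library, a signal that is never negative, in RPM, that is, reads scaled to a common total of the reads assigned to the listed small RNAs. Each lists 1018 entries, of which 473 carry human miRNA names, 378 mouse names and 167 a genomic locus number without a miRNA name. In this mouse study 99.2% of the control signal and 99.3% of the STZ signal stand under human names and 0.548% and 0.506% under mouse names, and no sequences were compared here, so a human name is a name only. Several miRNAs have reads under both a human and a mouse name, and sums over such counterparts were added after the files were seen. A further entry with no name is the sum of the 66 entries above it, equal to 96.5% and 96.6% of the totals, and stayed out of all sizes and tests. The unnamed loci held 2320 and 2230 RPM and were left out of the main counts. Of the 1018 entries, 475 were at 0 in both libraries, 370 of them named.

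The values are whole multiples of 1 read in each library. Dividing by that step gave whole reads for 100.0% of the deposited values, within 0.001 of a read, and totals of 508182 reads for the control and 706860 for the STZ library. The plan assumed counts. As the deposited signal is normalized, the rule planned for that case was the main one: a miRNA was higher or lower with at least a 2-fold difference of log2(value + 1), among named miRNAs with a mean of at least 10 RPM, with no interval. Such a fold understates the change of low miRNAs. The recovered reads gave exact 95% intervals of the STZ to control ratio (conditional binomial, Clopper-Pearson), Wilson intervals of shares, exact Poisson intervals of levels and exact intervals of the odds ratio of arms. They also gave an alternative call, added after the data were seen, with at least 20 reads over both libraries, a 2-fold ratio and an interval excluding 1. Folds against 0 used a floor of 3 reads per library, which gives larger bounds than the exact 95% interval of the ratio. With 1 library per group, edgeR's test could not be fitted for want of residual degrees of freedom, and no p-value is given.

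The lists of miRNAs, the rule for named miRNAs, the thresholds and most alternative settings were fixed before the data were examined. The rule names the 10 most abundant miRNAs, the 10 with the largest fold in each direction, the 3 highest per library that are at 0 in the other, and all list members. For the largest folds it set a mean of at least 10 RPM for a normalized signal, or 100 reads over both libraries for counts. Both minimums were used here, although the plan gave them as alternatives. The lists cover muscle, mitochondrial, let-7, miR-30, fibrosis-associated, miR-15/16, miR-17-92, miR-23/27/24, miR-181, miR-34/200 and stress, endothelial, smooth muscle and fibroblast, erythroid, leukocyte, liver, neural and islet, and imprinted Dlk1-Dio3 miRNAs. Because the files use human names, mouse names of list members were matched to their human counterparts by a table written after the files were seen, and the highest entry of a mature name was used, except that miR-322-5p was matched to its mouse-named entry and not to miR-424-5p. miR-199a-3p and miR-199b-3p had nearly equal reads (1471 and 1470 in the control, 2028 and 2022 in the STZ library, within 1%), so the same reads appear to count under both names, and likewise for miR-365a-3p and miR-365b-3p. For each list the median log2 fold is given with a counting interval from 1000 resamplings of the reads and with its percentile among 10000 random lists of the same size matched on mean level. These describe the 2 libraries and do not test the treatment. Members of the random lists were drawn independently, whereas some list members share a precursor or a cluster. A percentile can therefore look more extreme than the number of independent members allows. Setting members at 0 to the floor left every list median as it was.

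Scaling alternatives used TMM factors (edgeR 4.0.16), the median of ratios (DESeq2 1.42.0) and totals without the 10 most abundant miRNAs. Other alternatives changed the minimum level, the fold, the pseudocount, the handling of several entries of a mature name, and the depth by thinning. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 were used. Tested on simulated Poisson reads for the 851 named entries at the depths of the STZ and control libraries, the fold rule called 43.3% of 30 miRNAs with a true 2-fold difference, 100.0% of 30 with a 4-fold difference and 4.38% of 251 unchanged ones. The rule on recovered reads called 33.3%, 96.7% and 0.459% (of 218 unchanged). The simulation holds no variation between animals or from PCR. Gene positions come from the GENCODE mouse annotation on GRCm38, not the build of the study, and were not converted.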

Results

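Small RNA of cardiac mitochondria was sequenced from 1 control mouse heart library and 1 library from the heart of mice given STZ (streptozotocin, a toxin of pancreatic beta cells used to induce diabetes in mice). The study concerns diabetic cardiomyopathy, and its design sets the mitochondrial microRNA (miRNA) profile of the STZ heart against that of the control heart. The control library held 508182 assigned reads and the STZ library 706860. Levels are given as RPM, the reads of an entry scaled to a common library total. A single read equalled 1.97 RPM in the control and 1.41 in the STZ library, so a floor of 3 reads stood at 5.90 and 4.24 RPM. Of the named miRNAs, 393 had a value above 0 in the control and 407 in the STZ library, with 319 above 0 in both, 74 in the control alone and 88 in the STZ library alone. With 1 library per group no difference had a replicate check, no p-value was possible, and "higher" and "lower" below compare these 2 libraries, not the conditions. The 95% intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

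The same few miRNAs supplied most reads in both libraries, and the muscle list held 29.1% of control reads and 32.3% of STZ reads. The muscle-specific miR-1-3p, which restrains growth genes in cardiomyocytes, made up 20.9% of control reads (Wilson 95% interval 20.8 to 21.0) and 25.3% of STZ reads (25.2 to 25.4), an STZ to control ratio of 1.21 (1.20 to 1.22). Its partner in the same clusters, miR-133a-3p, had a ratio of 0.866 (0.854 to 0.879). The 10 most abundant miRNAs took 65.9% of control reads (65.8 to 66.0) and 65.8% of STZ reads (65.7 to 65.9), and 9 of the 10 were shared, with miR-24-3p in the control's 10 alone and miR-125b-5p in those of the STZ library. By mean share over both libraries, the next were miR-30a-5p (ratio 0.890), miR-143-3p (0.840), miR-30d-5p (1.14), miR-126-3p (0.639), miR-26a-5p (1.05), miR-30c-5p (0.912), miR-30e-5p (0.915) and miR-378a-3p, whose ratio of 0.986 had an interval (0.962 to 1.01) that included 1. None of the 32 miRNAs with at least 5000 reads over both libraries was 2-fold apart, and their log2 folds lay between -0.65 and 0.77. Across the 275 miRNAs with at least 20 reads over both libraries, Spearman's rho between the libraries was 0.880, a value across miRNAs, which are not independent replicates.

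By contrast, miRNAs known from liver and several of the epithelial miR-200 family stood lower in the STZ library. Liver-enriched miR-122-5p went from 787 RPM (400 reads) in the control to 73.6 (52 reads), 10.7-fold lower, and its STZ to control ratio of 0.0935 had an interval of 0.0686 to 0.125. The clustered miR-194-5p, miR-192-5p and miR-215-5p, abundant in liver, gut and kidney, were 3.41-fold (2.96 to 3.93), 2.45-fold (2.12 to 2.85) and 5.74-fold (3.85 to 8.80) lower. Epithelial miR-200b-3p had 57 reads in the control and 3 in the STZ library, a ratio of 26.4 (8.60 to 132) in favour of the control, and miR-200a-3p (32 and 4 reads) and miR-200c-3p (24 and 4 reads) lay in the same direction. Of the rest of that family, miR-141-3p had 0 and 4 reads, the mouse-named entry of miR-429-3p 2 and 7, and the human-named miR-429 2 and 0 (miR-429 chosen after its values were seen). In the opposite direction, miR-208b-3p, a miRNA encoded in the slow myosin gene Myh7, had 0 reads in the control and 59 in the STZ library (83.5 RPM), at least 14.1-fold higher against the floor of 3 control reads. The exact interval of its ratio had a lower bound of 11.1.

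**Figure D1:**
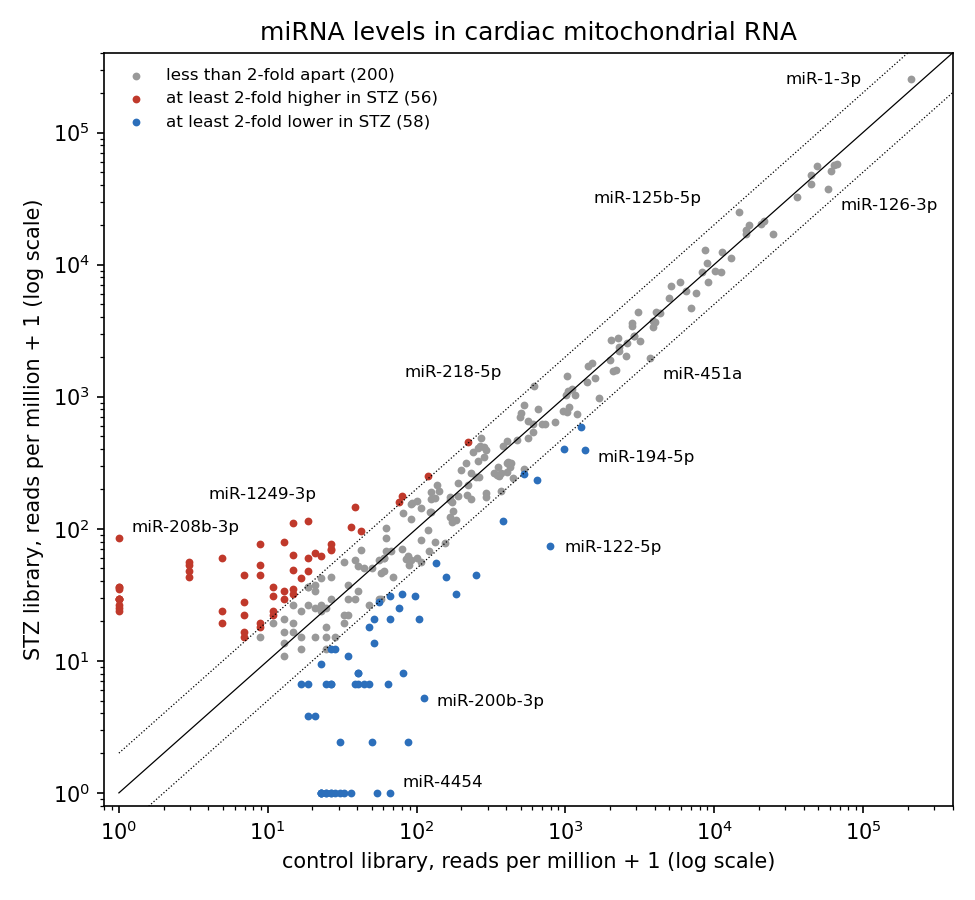
Each point is 1 of 314 tested miRNAs, with its level in the control library on the x axis and in the STZ library on the y axis, both in RPM plus 1 on log scales, the solid line marking equality and the dotted lines 2-fold. Most miRNAs (200, grey) lie within 2-fold, while 56 (red) lie above and 58 (blue) below, mainly at low levels.

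In all, 314 named miRNAs had a mean of at least 10 RPM. Of these, 56 were at least 2-fold higher and 58 at least 2-fold lower in the STZ library on the scale of log2(RPM + 1), and 200 (63.7%) were neither. The median log2 fold was -0.02. The higher miRNAs together held 0.103% of control reads and 0.351% of STZ reads, and the lower ones 0.871% and 0.260%. Of the 120 miRNAs with 20 to 99 reads, 67 (55.8%) were 2-fold apart, against 16 (10.3%) of the 155 with at least 100 reads. Among those tested, 11 of the higher miRNAs were at 0 in the control and 14 of the lower ones were at 0 in the STZ library. When an exact interval of the ratio also had to exclude 1 beside this fold, 48 were higher and 53 lower. The alternative call on recovered reads gave 42 higher and 37 lower. It also sets a minimum of 20 reads over both libraries and uses no pseudocount.

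Among miRNAs with at least 100 reads, 5 were higher in the STZ library and 11 lower. The higher ones were miR-1249-3p (19 and 102 reads, ratio 3.86, 2.35 to 6.67), let-7j (2.23, 1.55 to 3.27), miR-9985 (2.12), miR-9-5p (2.12, 1.45 to 3.15) and miR-340-5p (2.04, 1.64 to 2.55). Next in size but under 2-fold were miR-218-5p (1.97, 1.73 to 2.26), which is encoded in introns of the axon guidance genes Slit2 and Slit3, miR-98-5p (1.78), miR-125b-5p (7516 and 17800 reads, 1.70, 1.66 to 1.75), miR-181c-5p (1.70) and miR-7-5p (1.68). After miR-122-5p, the lower ones included miR-424-5p (5.88-fold, 3.66 to 9.83), miR-455-3p (3.71-fold), miR-5100 (3.37-fold), the inflammation-induced miR-146a-5p (2.77-fold, 2.29 to 3.35), miR-132-3p (2.49-fold) and miR-152-3p (2.16-fold, 1.91 to 2.45).

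Away from these, the largest differences rested on few reads in 1 library and 0 in the other. After miR-208b-3p, the highest STZ values were miR-197-3p and miR-196a-5p (25 reads each, at least 5.99-fold), miR-326 (24 reads, at least 5.75-fold, although its mouse-named entry had 2 control reads, which gave a summed ratio of 8.63 with an interval of 2.14 to 75.3), and miR-148a-5p, miR-96-5p, miR-6899-3p and miR-12199-3p (20 reads each, at least 4.79-fold). They were followed by miR-1947-5p (18 reads, at least 4.31-fold) and miR-7051-5p (17 reads, at least 4.07-fold). At 0 in the STZ library were miR-4454 (33 control reads, at least 15.3-fold lower), miR-127-5p (27 reads, at least 12.5-fold), miR-299-3p (18 reads, at least 8.35-fold), miR-5695 (16 reads, at least 7.42-fold) and miR-183-5p (12 reads, at least 5.56-fold). The same held for the mouse-named entries of miR-215-5p (15 reads, at least 6.95-fold), miR-192-5p (14 reads, at least 6.49-fold), and miR-450b-5p and miR-742-5p (13 reads each, at least 6.03-fold). The human-named entries of miR-215-5p and miR-192-5p did have STZ reads. Summed over both names, miR-215-5p had 143 and 31 reads (6.42-fold lower) and miR-192-5p 515 and 284 (2.52-fold lower). miR-362-5p had 44 control reads and 1 STZ read, a ratio of 61.2 with a wide interval (10.4 to 2472). Folds given as "at least" stand against the floor of 3 reads. Their exact lower bounds were smaller, for example 4.52 for miR-197-3p and 11.8 for miR-4454.

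Apart from miR-208b-3p, most heart muscle miRNAs showed small differences, in both directions. Of the muscle list, 8 of 11 members were measured, with miR-208b-3p higher and the other 7 less than 2-fold apart, 3 intervals lay above 1, 4 below and 1 included it, and the median log2 fold was -0.19 (counting interval -0.26 to -0.08), at the 18.2 percentile of 10000 random lists matched on mean level. miR-208a-3p, encoded in the adult myosin gene Myh6, had 78 control and 54 STZ reads (ratio 0.498, upper bound 0.713), just short of 2-fold on the scale used for calls. miR-499a-5p, encoded in Myh7b, had a ratio of 1.07 (1.02 to 1.14). By the mouse annotation on GRCm38, Mir208a lies on chromosome 14 at 54949060 to 54949142 in an intron of Myh6, and Mir208b on the same chromosome at 54975700 to 54975776 in an intron of Myh7.

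miRNAs that earlier work described inside mitochondria did not move as a group. Of 14 measured among 18, 1 was higher (miR-338-3p, with 4 and 13 reads, ratio 2.34, 0.722 to 9.84) and 2 were lower (miR-146a-5p, and miR-494-3p with 11 control reads and 0 STZ reads). Their median log2 fold was 0.01 (60.2 percentile), and its sign changed with the scaling. miR-181c-5p, which targets the mitochondrially encoded cytochrome oxidase subunit mt-Co1, had a ratio of 1.70 (1.20 to 2.46), and miR-378a-3p, from an intron of the metabolic coactivator gene Ppargc1b, stood at 0.986.

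The endothelial and erythroid miRNAs had lower values in the STZ library without reaching 2-fold, and the leukocyte list had a median log2 fold below 0 as well. All 4 endothelial members had an interval below 1, with a median log2 fold of -0.49 (-0.58 to -0.37, 3.33 percentile), led by miR-126-3p at 58615 and 37447 RPM and miR-222-3p at 291 and 174. Mir126a lies on chromosome 2 at 26591357 to 26591429, in the endothelial gene Egfl7. The 4 erythroid miRNAs had a median of -0.81 (-1.04 to -0.42, 3.15 percentile), 3 of them with intervals below 1, and the red cell miRNA miR-451a had a ratio of 0.525 (0.490 to 0.563). The endothelial list holds both arms of miR-126 and the erythroid list both arms of miR-144, so the members are not all independent. The random lists behind the percentiles do not allow for this. Of 7 leukocyte miRNAs, 1 was lower (miR-146a-5p), and the median was -0.45 (10.5 percentile), while miR-142-5p had a ratio of 1.29 (0.947 to 1.76). The human-named entry of miR-155-5p, a miRNA induced in activated immune cells, had a ratio of 1.61 (1.15 to 2.28), but its mouse-named entry had 33 and 21 reads, and their sum gave 1.16 (0.873 to 1.54). The 7 smooth muscle and fibroblast miRNAs were all within 2-fold, with a median of -0.01 (66.7 percentile) whose sign changed with the scaling.

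All 3 liver miRNAs were lower, with a median log2 fold of -1.77 (upper bound of the counting interval -1.56), below the median of every one of the 10000 matched random lists, and their share of reads was 0.312% in the control and 0.0870% in the STZ library. Mir122 lies on chromosome 18 at 65248861 to 65248926, in an exon of an annotated long noncoding RNA. Mir192 and Mir194-2 lie together on chromosome 19 (6264844 to 6264932, and 6264643 to 6264728), and Mir215 and Mir194-1 on chromosome 1 (185313581 to 185313692, and 185313319 to 185313385). In the list of miR-34, miR-200 and stress miRNAs, 3 of 5 measured members were lower, those of the miR-200 family, with a median of -2.86 (-3.82 to -1.73, 0.240 percentile). That median was -1.80 with no minimum level, where miR-141-3p enters, and -0.75 at a mean of at least 100 RPM, where the miR-200 members drop out. The p53-responsive miR-34a-5p had a ratio of 0.590 (0.405 to 0.856) and the hypoxia-induced miR-210-3p one of 1.80 (0.518 to 7.85). Among 4 measured neural and islet miRNAs, miR-9-5p was higher, the islet miRNA miR-375-3p was lower (20 and 4 reads), and the median was 0.61 (0.36 to 0.82, 95.9 percentile).

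**Figure D2:**
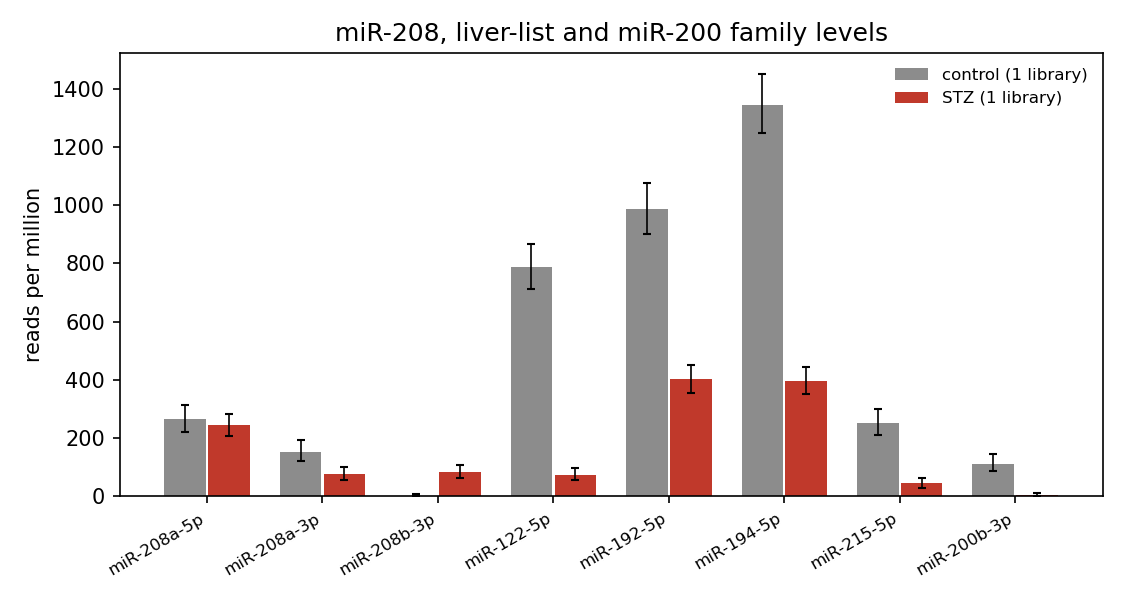
Bars give the level of 8 miRNAs in the control (grey) and STZ (red) library in RPM, 1 library each, with exact Poisson 95% intervals that cover counting error only. miR-122-5p stands at 787 and 73.6 RPM, and miR-208b-3p at 0 and 83.5.

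Members of the let-7 family, which mark differentiated cells, and the miR-29 family, which target collagen messages, had slightly higher values in the STZ library. None of the 9 let-7 members was 2-fold apart, but 7 had an interval above 1 and 1 below, and their median was 0.16 (0.14 to 0.37, 95.1 percentile). let-7a-5p had a ratio of 1.34 (1.28 to 1.41) and let-7c-5p one of 1.41. For the fibrosis-associated list, 8 of 9 were measured, none was 2-fold apart, and the median was 0.28 (0.10 to 0.41, 96.0 percentile). miR-29a-3p stood at 1.48 (1.43 to 1.54), while miR-21-5p had a log2 fold of -0.20.

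Of the remaining families, most had medians near or below equality, while the imprinted cluster had a median above it whose counting interval included 0. For the miR-30 family the median was -0.13 (21.8 percentile) with 0 of 7 apart by 2-fold, for the miR-23/27/24 clusters -0.04 (38.8 percentile) with 0 of 5, and for the miR-181 family 0.07 (62.6 percentile) with 0 of 4. The miR-15/16 family, which slows the cell cycle, had a median of -0.48 (15.95 percentile), with 1 of 6 lower (miR-322-5p, 28 and 19 reads under its mouse name, or 121 and 41 when summed with its human counterpart miR-424-5p, a summed ratio of 0.244, 0.167 to 0.350) and miR-16-5p at a ratio of 0.679 (0.648 to 0.713). The growth-associated miR-17-92 group had a median of -0.23 (29.9 percentile), with 1 of 8 measured members higher (miR-18a-5p, 5 and 15 reads, ratio 2.16, 0.745 to 7.59). In the imprinted Dlk1-Dio3 cluster, 9 of 25 members were measured, and 3 were higher (miR-434-3p with 7 and 77 reads, miR-543 with 1 and 37, and miR-379-5p with 21 and 67) and 2 lower (miR-134-5p with 15 and 1, and miR-541-5p with 13 and 8, ratio 0.442, 0.159 to 1.15). Its median was 0.68 (-0.21 to 1.04, 92.3 percentile). Opposite arms of listed members, which the list leaves out, went in both directions. For example, miR-127-5p had 27 and 0 reads, miR-299-3p 18 and 0, and miR-136-3p 9 and 42 (chosen after their values were seen). Some miRNAs belong to more than 1 list.

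**Figure D3:**
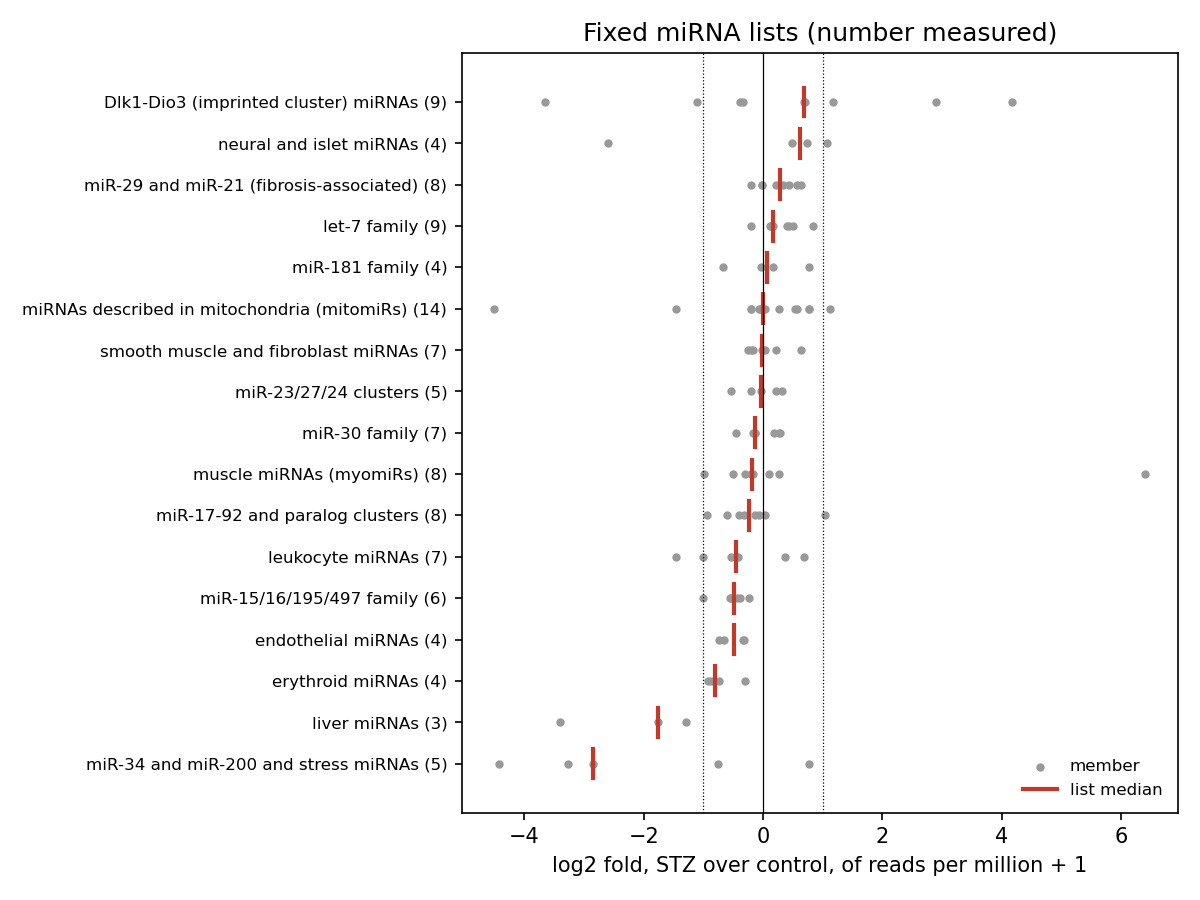
Each row is 1 of 17 fixed miRNA lists with the number of members measured, grey points are the members' log2 folds of STZ over control in RPM plus 1, and red bars are list medians, with dotted lines at 2-fold. The medians run from -2.86 for the list with the miR-200 family to 0.68 for the imprinted cluster, and the liver list stands at -1.77.

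Arm use, the ratio of the 5p to the 3p strand of a precursor, does not depend on the scaling between libraries. Of 49 precursors with at least 20 reads on each arm over both libraries, 17 differed by at least 2-fold in the arm ratio with an exact interval of the odds ratio excluding 1, 14 toward the 5p arm in the STZ library and 3 toward the 3p arm (miR-106b, miR-127 and miR-181a). The more abundant arm differed in 4 of the 49, of which miR-132 and miR-3068 were among the 17, whereas miR-145 and miR-1843a had nearly equal arms and intervals that included 1. The 5p and 3p arms of miR-132, a neuronal activity-responsive miRNA, had 6 and 68 reads in the control and 55 and 38 in the STZ library, and those of miR-98 had 138 and 52 against 342 and 14 (all precursors named here were chosen after their values were seen). Summing human-named and mouse-named entries left 16 precursors, 12 toward the 5p arm and 4 toward the 3p arm. miR-28 and miR-486a then no longer differed and miR-424 did. With at least 100 reads on each arm, 0 of 19 precursors differed by this rule.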

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

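The alternatives on recovered reads, with unnamed loci, without miRNAs at 0 in either library, with summed entries for list medians and arms, and a rank correlation at 10 RPM were chosen after the data were seen. No paired analysis was possible because each group had 1 library, which also rules out leaving libraries out. Scaling moved log2 ratios (before the pseudocount) by 0.03 (TMM), 0.01 (median of ratios) or -0.01 (without the 10 most abundant). Only calls near 2-fold turned. The 56 higher and 58 lower miRNAs became 57 and 56 under TMM and 56 and 57 under the median of ratios. Without the 10 most abundant they became 56 and 60. The log2 fold of miR-218-5p, 0.98 in the main setting, reached 1.01 under TMM. Signs changed for miR-378a-3p (log2 0.01 under TMM) and the medians of the mitochondrial and the smooth muscle and fibroblast lists, all near 0. The 56 higher and 58 lower miRNAs became 143 and 123 with no minimum level, 4 and 9 at a mean of 100 RPM, and 26 and 32 at 4-fold. With an interval required beside the fold they became 48 and 53. On recovered reads with an interval they became 42 and 37, where fewer low miRNAs pass by construction, 63 and 71 with unnamed loci, and 45 and 44 without miRNAs at 0 in either library. miRNAs with at least 10 reads numbered 252 in the control. The 5 most abundant miRNAs held 45.9% of control and 47.4% of STZ reads. The rank correlation was 0.779 with no minimum, 0.847 at 10 and 0.945 at 100 RPM. Arm ratios differed in 0 precursors with at least 100 reads per arm. For these shifts the cause was not tested, beyond the number of miRNAs each setting admits. Of 102 alternative list medians, 101 stayed within their counting interval and 1 did not, that of the miR-34, miR-200 and stress list (-0.75 at 100 RPM, where the miR-200 members fall under the minimum). Of 93 alternative log2 folds of named miRNAs, 84 stayed within theirs. The 9 that did not all belonged to the 10 most abundant miRNAs, for example miR-1-3p at 0.27 in the main setting and 0.30 under TMM. For these the shift by scaling exceeded the narrow counting interval. Thinning the STZ library to the control depth left a mean of 399 named miRNAs (393 to 406 over 100 draws), against 393 in the control. Depth limits what the miRNAs under 100 reads can show.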

Other observations

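In the following paragraphs the tests of liver RNA and of a single other tissue, all tests of the miR-208 pair and both tests of miRNAs at 0 were chosen after their results were seen, and the scaling test of the liver list was written before its result.

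Further epithelial and sensory-lineage miRNAs, singled out after their values were seen, did not all follow the miR-200 family. The human-named miR-182-5p had 22 reads in the control and 4 in the STZ library, or 22 and 6 when summed with its mouse-named entry. In the same cluster miR-183-5p had 12 and 0, whereas miR-96-5p, the remaining member of that cluster, had 0 and 20. The entry miR-4485-3p, whose human sequence matches the mitochondrial 16S ribosomal RNA, had 101 reads in the control and 197 in the STZ library, 199 and 279 RPM, a ratio of 1.40 (1.10 to 1.80). Among entries with no miRNA name, 29 loci had a mean of at least 10 RPM, 7 of them higher in the STZ library (6 at 0 in the control) and 13 lower (8 at 0 in the STZ library).

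The lower levels of miR-122-5p, miR-192-5p and miR-194-5p in the STZ library may come from more liver cells or liver RNA in the control preparation, but that all 3 list members had a ratio with an interval below 1 restates the pattern and does not decide this. Scaling moves all miRNAs alike, and the median log2 fold of those tested was -0.02 against -1.74 or lower for the liver list under the 3 scalings tried, which argues against it. A single tissue supplying all reads of these miRNAs would give them like ratios. The ratio of miR-122-5p had an upper bound of 0.125, below the lower bound of 0.351 for miR-192-5p. Their log2 gap of 2.12 was reached by 3.44% of pairs among 152 other miRNAs with at least 100 reads. This pair was the widest apart of the 3 members, and the intervals cover counting error only, so the gap does not decide the question. Carry-over on top of a heart level of miR-192-5p and miR-194-5p stays open, as do an additional epithelial source for the miR-200 family and an effect of STZ on the heart or on circulating miRNAs, none of which was tested. With 1 library per group a difference between preparations and a difference between treatments cannot be separated.

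miR-208b-3p and miR-208a-3p, products of neighbouring myosin genes with closely similar sequences, stood in opposite directions. Their summed level was 153 RPM in the control and 160 in the STZ library, a ratio of 1.04 (0.774 to 1.41). That interval includes 1, as it would if reads from the miR-208a arm were assigned to the miR-208b name. A balanced sum does not decide this. The control had 78 reads under miR-208a-3p and 0 under miR-208b-3p, against 54 and 59 in the STZ library. Such assignment would therefore have to differ between the libraries. Counting error is argued against, since 42.4 reads of miR-208b-3p would be expected in the control at the STZ level and 0 were listed. A lower level of the miR-208a precursor stays open as the cause of the lower miR-208a-3p. The ratio of miR-208a-3p had an upper bound of 0.713, just under the lower bound of 0.732 for miR-208a-5p. Of the 48 other precursors, 19 had an arm shift at least as large. Each of these had an arm with under 100 reads over both libraries. Among the 19 precursors with at least 100 reads on each arm, miR-208a included, its shift was the largest (log2 0.885). The shift of let-7b was nearly as large (-0.882), so the arms do not decide this. A rise of miR-208b with Myh7, known from stressed rodent hearts, stays open as a hypothesis, and neither Myh6 nor Myh7 messages were analysed here.

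Named entries at 0 in one library and at 10 reads or more in the other numbered 33, with 19 at 0 in the control and 14 at 0 in the STZ library. Under Poisson counting at the pooled rate the mean was 0.0820 such entries and the highest of 1000 simulations 2, so counting error alone is argued against. Splitting of reads between human-named and mouse-named entries is argued against for most, as 12.1% (4 of 33) had reads under another entry of the same miRNA in the library at 0. Uneven PCR amplification of few molecules, a read minimum or an assignment step in the authors' processing, and real differences between the hearts stay open, and none of them was tested.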
